A study of Mus musculus with 12 samples.

How the data were processed

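RNA from livers of male C57BL/6 mice was profiled by MeRIP-seq, in which fragmented RNA is immunoprecipitated with an antibody against N6-methyladenosine (m6A), a methyl mark on adenosines of RNA, and sequenced beside input RNA. The labels describe 12 libraries: 6 of immunoprecipitated RNA (IP) and 6 of input RNA, each set with 3 control samples (0 mg/kg/day CdCl2) and 3 cadmium samples (20 mg/kg/day CdCl2 by gavage) at day 90. Per the submitters' processing notes, the tools named were cutadapt 1.1.8, STAR 2.7.1a, SAMtools 1.3.1, MACS2 2.1.1 and DESeq2 4.1.0 (as written there, a number that may be a version of R), and the genome build was mm10. The notes give no role, order or setting for these tools. Per the labels' protocols, libraries were made with the Ovation SoLo kit and sequenced in paired reads on an Illumina NovaSeq. How duplicate reads and reads that match several places were handled is not given in the sources used here, and neither is whether the counting used strand.

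The deposited table lists 37118 peaks with chromosome, start, end and gene symbols, and 6 columns of raw counts, whole numbers per peak that the authors did not normalise as far as the values show. The authors' deposited table also gives a log2 fold change, a p-value and an adjusted p-value per peak and a call of Up, Down or none. These were used only for comparison. Whether the authors called peaks in each sample or in pooled samples is not given in the sources used here. The peaks form 1 common set counted in all 6 samples. The headers of the count columns are library numbers that the IP and the input library of a sample share. The columns were read as IP counts because the rows are m6A peaks, and this reading is an assumption. The group of each column is not in doubt. Input counts were not used here. A difference in peak counts can therefore come from the amount of RNA of the gene, from the methylated share, or from both.

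Genes were named as the table names them. Of 35563 peaks with a gene symbol, 2009 carried more than 1 symbol, and with the strand unknown the reads of overlapping genes could not be told apart. Among the named peaks this holds for A1bg, Mt2, Wee1, Usp2, Per3, Mvd, Hsd3b7, Slc2a2, Hspa8, Ccl2, Col4a1, Ciart, Lrat, Ccnd1, Rbm15b, Cbll1, Slc30a1, Hamp, Gclm, Irs2, B2m, Ciita, Gbp10, Cebpb and Acot3, each of which shares its peak with another symbol. Members of similar gene families (Cyp2a, Cyp2c, Cyp3a, Cyp4a, Saa, Mt, Sult3a, Gbp, Hspa1 and the alpha globins) may share reads, and their separate values are uncertain. Of 35100 annotated peaks whose symbol was found in the RefSeq gene table of assembly GRCm38.p6, 34721 overlapped that gene. Coordinates are given as deposited, on mm10. Whether the starts count from 0 is not given in the sources used here. Exon, intron and UTR positions, and the sequence motif of m6A, were not analysed here, because no genome sequence or transcript models were used.

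Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM normalisation, the filterByExpr filter (minimum count 10, minimum total count 15, which kept 37088 peaks) and the quasi-likelihood F test of 3 cadmium against 3 control samples. Peaks with a Benjamini-Hochberg adjusted p below 0.05 were called, with no minimum fold change. Levels are normalised counts scaled to a common library size (CPM) as mean ± SD with n = 3 samples per group. Log2 changes are cadmium relative to control with an approximate standard error (SE). The SE was derived as the absolute log2 change divided by the square root of the F statistic. It is therefore not independent of the p-value. Every adjusted p given for a peak is from this test unless another is named. The labels' protocol gives 6 animals per group, and how the 3 samples per group relate to them was not established here. The labels number the replicates but do not say outright that each is a separate mouse. The p-values therefore judge group differences against the spread between these samples. The biological coefficient of variation was 19.4%. No pair of replicates agreed within sampling noise: the chi-square of their counts per degree of freedom was 31.9 to 162.

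The labels name replicates 1, 2 and 3 as batches 1, 2 and 3, so equal numbers pair a cadmium with a control sample. Deviations from the group means correlated at 0.144, 0.212 and 0.171 across peaks within batches, and at -0.170 to 0.016 across batches. The fit with the replicate as a block is therefore an alternative with a basis in the design.

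Gene lists (24) were fixed before the data were examined: metal handling, NRF2 and antioxidant, m6A writers, erasers and readers, fatty acid oxidation and PPARA targets, lipogenesis and triglyceride storage, cholesterol synthesis and uptake, bile acid synthesis and transport, xenobiotic metabolism, glucose metabolism and insulin signalling, ER and integrated stress response, heat shock, p53 and apoptosis, autophagy and mitophagy, proliferation, inflammation and acute phase, fibrosis and matrix, circadian clock, and markers of hepatocytes, Kupffer cells and macrophages, liver endothelium, stellate cells, cholangiocytes, lymphocytes and neutrophils, and erythroid cells. Of their 363 gene entries 313 had a peak. Each gene was represented by its peak with the smallest p. Lists with at least 3 members (23 of 24) were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, and again with an estimated correlation. A list is called at an adjusted p below 0.05 with the preset value. With an estimated correlation 0 of 23 lists passed, 4 had an unadjusted p below 0.05, and the smallest adjusted p was 0.0855.

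The text names peaks by a rule fixed before the data were examined. It takes the 10 largest rises and the 10 largest falls among called peaks at or above the median level, 1 per gene, without predicted genes and pseudogenes, and up to 4 called members of each list by smallest p. Mt1, Mt2 and the m6A genes are named whatever their values. Other genes are named as chosen after their values were seen. Within genes, each peak was compared with the other peaks of its gene by edgeR's diffSpliceDGE, using 29951 peaks in 7063 genes with single-symbol peaks. The share of higher calls was tested per chromosome with Fisher's exact test, two-sided.

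The steps were tested on simulated counts with the means and library sizes of these samples, for cadmium against control. On 37088 peaks, the peak test recovered 52% of 2-fold and 96% of 4-fold changes, and 16 of its 164 calls were false. That share of false calls was above the 0.05 at which the adjusted p aims, so the calls here may also hold more false ones than that. Over 11805 genes, the list test ranked the changed list as number 1 and called 0 unchanged lists, but simulated peaks were independent. The within-gene test on 29951 peaks recovered 87.5% of 4-fold departures and called 16 of 28891 peaks in genes with no departure.

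Alternatives were the replicate block, DESeq2 1.42.0 size factors and test, no count filter, other thresholds, a minimum fold, only peaks at or above the median level, 1 peak per gene, and leaving out each sample in turn. Total counts without TMM, a fit without the largest 2 peaks, 1 peak per gene for chromosomes, and the block and leave-outs for list results were added after seeing the data. For the share of higher calls, only an adjusted p below 0.01, an unadjusted p below 0.05, the minimum fold and the median level were set beforehand.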

Results

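The m6A immunoprecipitation of liver RNA gave counts for 37118 peaks in 3 cadmium and 3 control samples, taken after 90 days of CdCl2 gavage at 20 or 0 mg/kg/day. Cadmium is a toxic metal that accumulates in liver and kidney, and the comparison asked which peaks and genes differ in livers exposed to it. Counts in peaks totalled 40174736, 51205200 and 50171237 in cadmium replicates 1, 2 and 3 and 52338612, 46474259 and 46572869 in control replicates 1, 2 and 3. Peaks had a median width of 229 bp (101 to 7462 bp) and a median of 2146 counts over the 6 samples. The 2 largest peaks, annotated to the predicted genes Gm12895 and Gm12896, took 4.95% to 19.7% of the counts of a sample. Peaks on the mitochondrial chromosome took 0.575% to 1.01%, and peaks without a gene 2.18% to 2.77%. The first principal component held 45.4% of the variance and separated the 2 groups.

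Cadmium and control livers differed at 2325 of 37088 tested peaks, of which 1317 were higher and 1008 lower in cadmium samples. These peaks lay in 1116 genes. A peak was called higher in 708 genes and lower in 410, and 2 genes, Rhobtb1 and Arhgap26 (which overlaps Fgf1), had calls in both directions. The change was at least 2-fold at 1161 peaks, 689 higher and 472 lower. Among called peaks at or above the median level, the steepest rises included the metallothioneins Mt1 and Mt2, which bind heavy metals, and the steepest falls included Tsku, which encodes a secreted protein made in liver, and Noct, Wee1 and Usp2, whose RNAs cycle over the day in liver. Without cadmium replicate 3 the count was 543, and without control replicate 3 it was 1078. Higher peaks made up 56.6% of calls (exact two-sided binomial p = 1.59e-10 over peaks, which are not independent). By the same exact test that share was 51.9% without cadmium replicate 3 (p = 0.391), 49.3% without control replicate 1 (p = 0.574), and 44.4% among peaks at or above the median level (p = 7.99e-05, a lean towards lower counts), so the lean towards higher counts did not hold across these choices.

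Genes of metal handling changed at 5 of 15 measured members, with 4 higher and 1 lower. Mt2 on chromosome 8 (94172853 to 94172963) rose 16.8-fold, from 12.6 ± 7.02 to 211 ± 20.4 CPM (SD, n = 3, log2 change 4.07, SE 0.34, adjusted p = 0.000844). Mt1 in the same metallothionein cluster (94179862 to 94180273), rose 10.1-fold, from 64.5 ± 32.4 to 652 ± 146 CPM (SD, n = 3, log2 change 3.34, SE 0.34, adjusted p = 0.00106). Tfrc, the transferrin receptor for iron uptake, was 6.70-fold lower (7.48 ± 1.91 in control and 1.12 ± 0.480 CPM in cadmium samples, SD, n = 3, log2 change -2.74, SE 0.30, adjusted p = 0.0012). The metal exporter Slc30a10 rose 1.85-fold (adjusted p = 0.0211) and the zinc exporter Slc30a1, chosen after its values were seen, rose by 0.96 on the log2 scale (SE 0.23, adjusted p = 0.038). The iron genes Fth1 (log2 change 0.17) and Hamp (-0.08) were not called. Adjusted over the list alone, 7 members passed. The list as a whole was not called (camera adjusted p = 0.112), but passed with the replicate block (adjusted p = 0.0141), without control replicate 3 (0.00476) and among genes at or above the median level (0.000819). Slc30a10 was not called without cadmium replicate 3 (adjusted p = 0.102), and Slc30a1 was not called without cadmium replicate 2 or 3 or control replicate 1 or 2 (0.064 to 0.172).

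Of 21 measured NRF2 and antioxidant genes, 1 rose and 0 fell. Hmox1, the haem-degrading enzyme induced by oxidative stress, rose 1.95-fold, from 1.93 ± 0.475 to 3.77 ± 0.716 CPM (SD, n = 3, log2 change 0.97, SE 0.24, adjusted p = 0.0406). The other members had log2 changes of both signs, 16 of 21 below 0, and edgeR found 6 of 21 at an unadjusted p below 0.05. DESeq2 called 4, adding Txnrd1, Gsta2 and Gsta4 as lower. Nqo1 (log2 change -0.49, adjusted p = 0.22), Gclc (-0.34) and Gclm (-0.08), classical targets of this pathway, were not called. Adjusted over the list alone, 0 members passed. The list test gave an adjusted p of 0.0633, or 0.00632, in the lower direction, without cadmium replicate 3. The call of Hmox1 was lost without cadmium replicate 2 or 3 or control replicate 1 or 3 (adjusted p 0.0998 to 0.136).

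**Figure D1:**
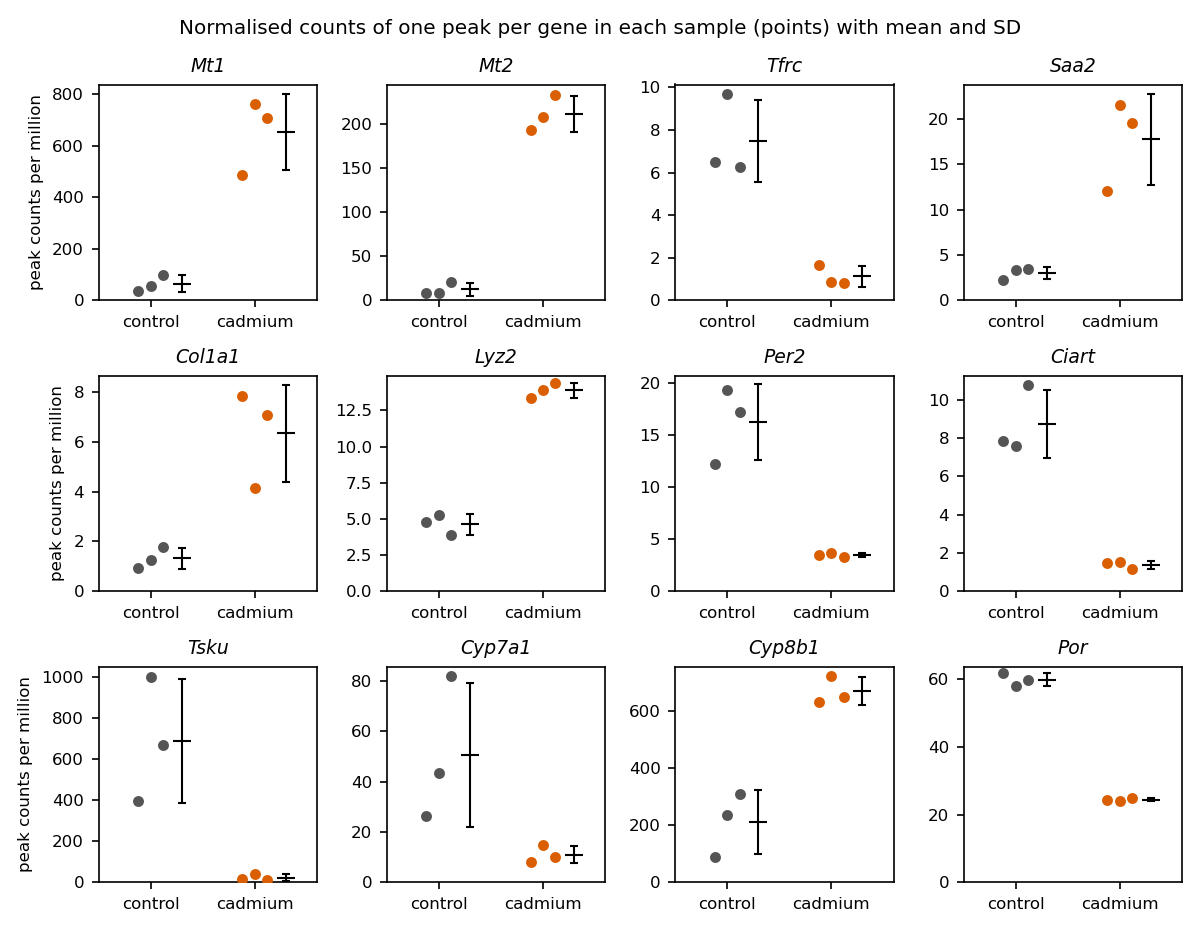
Normalised CPM (vertical axes, from 0) of the peak with the smallest p of 12 genes named in the text; each point is 1 of 3 control (grey) or 3 cadmium (orange) samples, and the black mark and bar are mean and SD. In all 12 genes the 3 cadmium values lay on one side of the 3 control values, as for Mt2 (mean 12.6 in control and 211 in cadmium samples) and Tsku (691 and 23.5).

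Circadian clock genes changed at 8 of 13 measured members, 6 lower and 2 higher, and 12 passed when adjusted over the list alone. Ciart, a repressor of the clock, was 6.28-fold lower (8.74 ± 1.77 in control and 1.39 ± 0.203 CPM in cadmium samples, SD, n = 3, log2 change -2.65, SE 0.21, adjusted p = 0.000832). The period genes Per2 (chromosome 1, 91424100 to 91424513, log2 change -2.21, SE 0.20, adjusted p = 0.000883) and Per3 (-2.01, SE 0.16, adjusted p = 0.000832) fell more than 4-fold, and so did the leading peak of Hlf, a transcription factor driven by the clock (-2.07, SE 0.26, adjusted p = 0.00199). That Hlf peak departed from the other 7 peaks of its gene, whose median log2 change was -0.77 (within-gene test by diffSpliceDGE, adjusted p = 0.0425). Chosen after their values were seen, Per1 (-1.72, SE 0.28) and Tef (-1.24, SE 0.17) were also lower, while the repressors Nr1d1 (1.58, SE 0.25, adjusted p = 0.00636) and Nfil3 (0.66, SE 0.16, adjusted p = 0.0325) were higher. The list was lower as a whole (camera adjusted p = 1.88e-08, and adjusted p = 0.0855 with an estimated correlation). The call of Nfil3 was kept only without control replicate 2, with adjusted p up to 0.142 in the other 5 leave-outs.

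Among called peaks at or above the median level, the largest falls included genes outside that list. Tsku on chromosome 7 (98350677 to 98353075) was 29.3-fold lower (691 ± 304 in control and 23.5 ± 16.9 CPM in cadmium samples, SD, n = 3, log2 change -4.87, SE 0.52, adjusted p = 0.0012). Noct, which encodes the rhythmic enzyme nocturnin, was 21.4-fold lower (chromosome 3, 51224624 to 51225012, log2 change -4.42, SE 0.36, adjusted p = 0.000832), and Wee1, a cell cycle kinase gene, 15.7-fold lower (chromosome 7, 110121190 to 110122195, -3.97, SE 0.36, adjusted p = 0.000883). Alas1, the rate-limiting enzyme of haem synthesis, fell from 98.5 ± 11.5 to 10.1 ± 5.20 CPM (SD, n = 3, -3.28, SE 0.31, adjusted p = 0.000966). Usp2 (-3.28, SE 0.40), Coq10b (-2.55, SE 0.27) and the kinase gene Sik1 (-2.21, SE 0.29) were also among the 10 genes with the largest falls at that level, as were Per2, Per3 and Cyp7a1. Without cadmium replicate 2 the log2 changes of Tsku and Usp2 were -5.63 and -4.03. Among the largest rises at that level, A1bg on chromosome 15 (60917659 to 60918075) went from 1.57 ± 0.760 to 38.7 ± 14.8 CPM (SD, n = 3, log2 change 4.63, SE 0.40, adjusted p = 0.000868). The water channel gene Aqp8 (2.13, SE 0.41), Fam129b (2.54, SE 0.26), Zc3h12d (2.08, SE 0.33), Cables1 (2.08, SE 0.22) and the fatty acid binding protein gene Fabp5 (2.73, SE 0.54) also rose. Aqp8 was not called without cadmium replicate 3 (adjusted p = 0.0517), nor Fabp5 without control replicate 3 (adjusted p = 0.0723), and without control replicate 1 the log2 change of Fabp5 was 3.58.

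Bile acid genes moved in opposite directions, with 2 higher and 3 lower of 19 measured and 5 when adjusted over the list alone. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 4.60-fold lower (chromosome 4, 6267087 to 6267499, 50.6 ± 28.5 in control and 10.99 ± 3.37 CPM in cadmium samples, SD, n = 3, log2 change -2.20, SE 0.37, adjusted p = 0.00838). Cyp8b1, the sterol 12-alpha-hydroxylase needed for cholic acid, rose 3.17-fold (chromosome 9, 121914371 to 121916258, 211 ± 112 to 669 ± 48.6 CPM, SD, n = 3, log2 change 1.66, SE 0.34, adjusted p = 0.0197). Hsd3b7, which acts early in the same pathway, rose 2.07-fold (adjusted p = 0.00481), and the bile acid receptor gene Nr1h4 was lower (log2 change -0.63, SE 0.15, adjusted p = 0.0363). The remaining call, Cyp27a1, chosen after its values were seen, was lower (-0.74, SE 0.18, adjusted p = 0.0387). The list as a whole was not called (camera adjusted p = 0.112, or 0.0272, in the lower direction, without cadmium replicate 1). Cyp8b1 was not called without cadmium replicate 3 (adjusted p = 0.0643), Cyp27a1 not without cadmium replicate 2 or 3 or control replicate 3 (0.115 to 0.172), and Nr1h4 was called in 1 of 6 leave-outs, that without control replicate 1 (up to 0.196 in the others).

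Cholesterol synthesis genes rose at 3 of 19 measured members and fell at 0, and 8 passed when adjusted over the list alone. Mvd, an enzyme of the mevalonate pathway, rose 2.72-fold, from 15.5 ± 1.66 to 42.1 ± 9.57 CPM (SD, n = 3, log2 change 1.44, SE 0.19, adjusted p = 0.00265). Hmgcs1, the synthase at the start of that pathway (log2 change 1.04, SE 0.21, adjusted p = 0.0191), and Msmo1, a late enzyme of it (0.86, SE 0.17, adjusted p = 0.0183), also rose. The list was called higher (camera adjusted p = 0.00159, and adjusted p = 0.502 with an estimated correlation), but not without cadmium replicate 1 (adjusted p = 0.159). Msmo1 was not called without cadmium replicate 3 (adjusted p = 0.0611), nor Hmgcs1 without cadmium replicate 1 or 3 or control replicate 2 (0.0506 to 0.0734).

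Fatty acid oxidation genes and PPARA targets fell at 3 of 21 measured members, also when adjusted over the list alone, and 19 of 21 log2 changes were below 0. The microsomal fatty acid hydroxylases Cyp4a14 (110 ± 37.9 in control and 33.6 ± 12.0 CPM in cadmium samples, SD, n = 3, log2 change -1.71, SE 0.30, adjusted p = 0.00956) and Cyp4a10 (-1.48, SE 0.37, adjusted p = 0.0414) and the thioesterase Acot1 (-1.20, SE 0.18, adjusted p = 0.00529) were lower. Mitochondrial enzymes such as Cpt2 (-0.30) and Acadm (-0.38) were not called. The list was lower as a whole (camera adjusted p = 0.000152, and adjusted p = 0.317 with an estimated correlation). Lipogenesis genes fell at 2 of 20 members, Thrsp (-1.46, SE 0.37, adjusted p = 0.0428) and the regulator Srebf1 (-0.85, SE 0.22, adjusted p = 0.0437), and at 0 when adjusted over the list alone. Their median log2 change was 0.03 while the mean (-0.14) and the test (camera adjusted p = 0.258) pointed lower, and the test passed without cadmium replicate 1 (0.00508) or control replicate 2 (0.0305). Cyp4a14 was not called without cadmium replicate 3 (adjusted p = 0.0542), nor Cyp4a10 without cadmium replicate 1 or 3 or control replicate 2 or 3 (0.105 to 0.16), nor Thrsp without cadmium replicate 2 or 3 or control replicate 1 or 3 (0.0661 to 0.165). Srebf1 was called in 1 of 6 leave-outs, without control replicate 1 (up to 0.191 in the others), and not with the replicate block (adjusted p = 0.0577).

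Xenobiotic metabolism genes fell at 7 of 19 measured members and rose at 0, with 10 when adjusted over the list alone and 18 of 19 log2 changes below 0. Por, the reductase that supplies electrons to microsomal cytochrome P450 enzymes, fell from 59.7 ± 1.93 to 24.4 ± 0.473 CPM (SD, n = 3, chromosome 5, 135723147 to 135723303, log2 change -1.29, SE 0.14, adjusted p = 0.00112). Cyp2a5 (-1.10, SE 0.15, adjusted p = 0.00284), Cyp2c50 (-0.74, SE 0.17, adjusted p = 0.0312) and the xenobiotic receptor gene Nr1i3 (-0.67, SE 0.15, adjusted p = 0.0252) were also lower. The list was called lower (camera adjusted p = 9.49e-07, and adjusted p = 0.0855 with an estimated correlation). Nr1i3 was not called without cadmium replicate 2 or 3 or control replicate 2 or 3 (adjusted p 0.0504 to 0.152), nor Cyp2c50 without cadmium replicate 2 or 3 or control replicate 1 or 2 (0.0552 to 0.146).

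Genes of glucose metabolism and insulin signalling fell at 5 of 16 measured members, with 7 when adjusted over the list alone. Tat, the tyrosine aminotransferase of amino acid breakdown, was 2.04-fold lower (247 ± 30.4 in control and 121 ± 15.0 CPM in cadmium samples, SD, n = 3, log2 change -1.03, SE 0.16, adjusted p = 0.00505). Pck1, a key enzyme of glucose production (-0.997, SE 0.18, adjusted p = 0.0126), its transcriptional activator Foxo1 (-0.66, SE 0.15, adjusted p = 0.031) and the glucose transporter Slc2a2 (-0.63, SE 0.16, adjusted p = 0.0462) were lower. The remaining call, Igfbp1, chosen after its values were seen, was lower as well (-1.64, SE 0.43, adjusted p = 0.0467). The insulin receptor gene Insr (0.50) and Irs2 (0.42) were not called. The list was lower as a whole (camera adjusted p = 0.00388, and adjusted p = 0.152 with an estimated correlation). Pck1 was not called without cadmium replicate 3 (adjusted p = 0.0606). Foxo1 and Igfbp1 were called only without control replicate 1, and Slc2a2 only without cadmium replicate 1 (adjusted p up to 0.206 in the other leave-outs).

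Heat shock genes fell at 5 of 11 measured members, with 9 when adjusted over the list alone, and all 11 log2 changes were below 0. The chaperone gene Hsph1 was 3.68-fold lower (9.44 ± 1.02 in control and 2.56 ± 0.0745 CPM in cadmium samples, SD, n = 3, log2 change -1.88, SE 0.17, adjusted p = 0.000883). Hspa8, the constitutive member of the HSP70 family (-0.95, SE 0.13, adjusted p = 0.00374), Hsp90aa1 (-0.95, SE 0.16, adjusted p = 0.00936) and Dnajb1 (-0.82, SE 0.16, adjusted p = 0.0173) were lower, as was Hspd1 (-0.55, SE 0.14, adjusted p = 0.0457), chosen after its values were seen. The list was called lower (camera adjusted p = 5.19e-08, and adjusted p = 0.152 with an estimated correlation). In the ER and integrated stress list 1 of 19 members rose, 2 fell, and 3 passed when adjusted over the list alone. Trib3, a pseudokinase gene induced by ATF4, rose 3.52-fold (14.9 ± 2.69 to 52.6 ± 10.4 CPM, SD, n = 3, adjusted p = 0.0012), whereas Herpud1 (-0.85, SE 0.13, adjusted p = 0.00619) and Dnajb9 (-0.84, SE 0.20, adjusted p = 0.0354), targets of the unfolded protein response, were lower. This list was not called (camera adjusted p = 0.345). Hspd1 was called only without control replicate 2 (adjusted p up to 0.171 in the others). Dnajb1 was not called without cadmium replicate 1 or 3 (adjusted p 0.0507 and 0.0903), nor Herpud1 without cadmium replicate 3 (0.0532), nor Dnajb9 without cadmium replicate 1, 2 or 3 or control replicate 2 (0.0677 to 0.155).

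**Figure D2:**
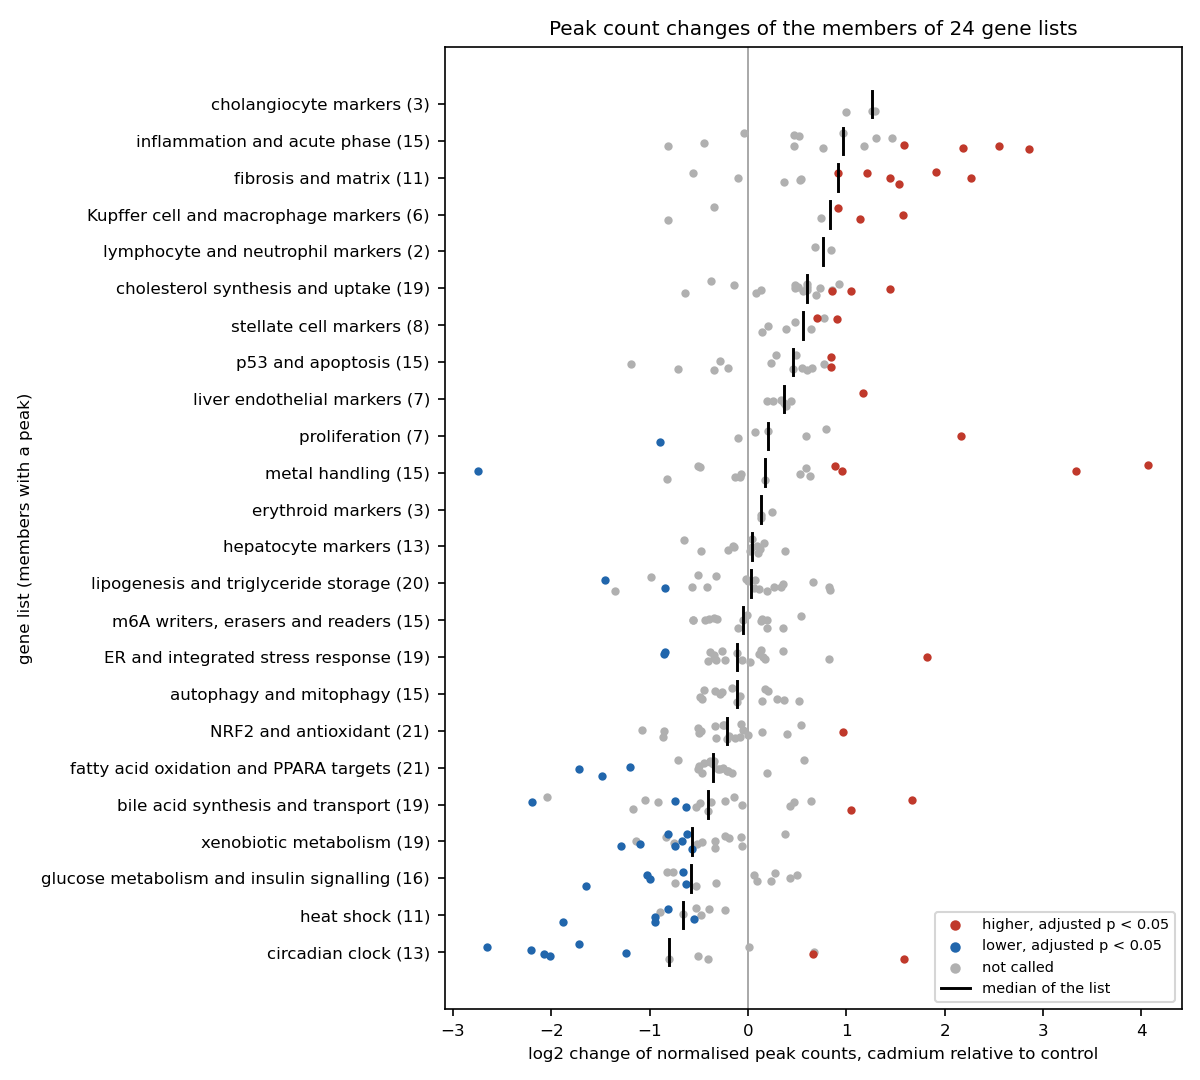
Log2 change of normalised peak counts in cadmium relative to control samples (horizontal axis) for the members of 24 gene lists (vertical axis, with the number of members that had a peak), using the peak with the smallest p of each gene. Red and blue points were called higher and lower, grey points were not called, and the black bar is the median of the list, from -0.80 for the circadian clock to 1.26 for 3 cholangiocyte markers of which 0 were called.

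Inflammation and acute phase genes rose at 4 of 15 measured members and fell at 0, with 11 when adjusted over the list alone. The serum amyloid genes Saa2 (3.04 ± 0.654 to 17.8 ± 5.03 CPM, SD, n = 3, chromosome 7, 46752308 to 46752475, log2 change 2.55, SE 0.25, adjusted p = 0.00106) and Saa1 (2.19, SE 0.29, adjusted p = 0.00281), major acute phase proteins of mouse liver, rose 5.85-fold and 4.55-fold. The chemokine gene Ccl2 was at 0.128 ± 0.133 in control and 0.968 ± 0.169 CPM in cadmium samples (SD, n = 3, log2 change 2.86, SE 0.63, adjusted p = 0.0257), with 0 counts in 1 sample, and the pattern receptor gene Tlr2 rose by 1.58 on the log2 scale (SE 0.34, adjusted p = 0.0223). The acute phase gene Hp was not called (-0.04). The list was called higher (camera adjusted p = 2.37e-05, and adjusted p = 0.238 with an estimated correlation). Of 6 markers of Kupffer cells and macrophages, 3 were called higher in the same samples and 2 had changes below 0. Ccl2 was not called without cadmium replicate 2 or 3 or control replicate 2 (adjusted p 0.0512 to 0.0957), and its log2 change without control replicate 1 was 3.89. Tlr2 was not called without cadmium replicate 2 or 3 or control replicate 3 (0.0502 to 0.0926).

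Fibrosis and matrix genes rose at 6 of 11 measured members and fell at 0, also when adjusted over the list alone. The 4 collagen genes of the list all rose. Col1a1 went from 1.32 ± 0.419 to 6.34 ± 1.94 CPM (SD, n = 3, chromosome 11, 94951281 to 94951624, log2 change 2.26, SE 0.30, adjusted p = 0.00268). Col3a1 (1.91, SE 0.26, adjusted p = 0.00314), Col4a1 (1.54, SE 0.18, adjusted p = 0.00183) and Col1a2 (1.44, SE 0.24, adjusted p = 0.00838) rose beside it. Fn1, which hepatocytes also make, was not called (-0.10). The list was called higher (camera adjusted p = 2.88e-06, and adjusted p = 0.264 with an estimated correlation). Stellate cell markers, of the cells that lay down collagen in liver, had a median log2 change of 0.56 in the same samples.

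Markers of liver cell types other than hepatocytes were higher in several lists. Kupffer cell and macrophage markers rose at 3 of 6 measured members (5 adjusted over the list alone). Lyz2 rose from 4.64 ± 0.711 to 13.9 ± 0.504 CPM (SD, n = 3, log2 change 1.58, SE 0.17, adjusted p = 0.00112), Cd5l by 1.14 (SE 0.22, adjusted p = 0.0158) and Csf1r by 0.92 (SE 0.19, adjusted p = 0.0199) on the log2 scale, while Vsig4 (-0.81, adjusted p = 0.155) and Marco (-0.35) were not called. That list was called (camera adjusted p = 0.011, and adjusted p = 0.442 with an estimated correlation), but not without control replicate 3 (adjusted p = 0.107). Stellate markers rose at 2 of 8 members (4 over the list alone), Lrat (0.91, SE 0.19, adjusted p = 0.0208) and Colec11 (0.70, SE 0.18, adjusted p = 0.0486), and the list was called (camera adjusted p = 0.00897, and adjusted p = 0.288 with an estimated correlation). Endothelial markers rose at 1 of 7 members (0 over the list alone, unadjusted 1, DESeq2 1), Lyve1 (1.17, SE 0.29, adjusted p = 0.039), with the list not called (camera adjusted p = 0.0863, or 0.00371 without cadmium replicate 3). Of 3 cholangiocyte markers edgeR called 0 and DESeq2 2 (Sox9 and Spp1, both higher), with 3 at an unadjusted p below 0.05 and 3 over the list alone (camera adjusted p = 0.0632, but 4.92e-06 without cadmium replicate 2 and 0.0451 without control replicate 3). Cd5l was not called without cadmium or control replicate 3, Csf1r not without cadmium replicate 2 or 3 or control replicate 3, and Lrat not without cadmium replicate 2 or 3 or control replicate 2 or 3 (adjusted p 0.0533 to 0.113). Lyve1 and Colec11 were each called in 1 of 6 leave-outs, without control replicate 1 and without cadmium replicate 1 (adjusted p up to 0.172 in the others).

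Hepatocyte markers were called at 0 of 13 members by edgeR and at 2 by DESeq2 (Cps1 and Hnf4a, both lower), with 3 at an unadjusted p below 0.05 and 0 over the list alone. Alb, the most abundant plasma protein gene, had 611 ± 38.8 CPM in control and 548 ± 115 CPM in cadmium samples (SD, n = 3, log2 change -0.16, SE 0.17, adjusted p = 0.642). The median log2 change of these markers was 0.04, against a mean of -0.05 and a test in the lower direction (camera adjusted p = 0.488). Of 3 erythroid markers (camera adjusted p = 0.882) and 2 lymphocyte and neutrophil markers (too few to test), edgeR and DESeq2 called 0, with 0 at an unadjusted p below 0.05 and 0 over the list alone.

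The m6A writers, erasers and readers were called at 0 of 15 measured members by edgeR, with 3 at an unadjusted p below 0.05 and 0 over the list alone, and at 1 by DESeq2, the reader Ythdf3. Ythdf3 had 29.6 ± 5.60 CPM in control and 20.1 ± 2.22 CPM in cadmium samples (SD, n = 3, log2 change -0.56, SE 0.18, adjusted p = 0.088). The demethylase Alkbh5 (-0.56, SE 0.19, adjusted p = 0.116) and the reader Ythdf1 (-0.44, SE 0.18, adjusted p = 0.187) were the others with a small unadjusted p. The writer components Mettl16 (-0.01), Wtap (0.14), Virma (0.20), Rbm15 (0.20), Rbm15b (-0.39), Zc3h13 (-0.34) and Cbll1 (-0.10), the demethylase Fto (0.36) and the readers Ythdf2 (-0.32), Ythdc1 (0.54), Hnrnpa2b1 (-0.05) and Hnrnpc (0.13) were not called, with adjusted p from 0.259 to 0.987. The list test gave an adjusted p of 0.345. The rest of the 21 genes fixed for this list had no peak under their symbol and were not tested. They are the writers Mettl3 and Mettl14 and the readers Ythdc2, Igf2bp1, Igf2bp2 and Igf2bp3.

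In the p53 and apoptosis list 2 of 15 members rose and 3 passed over the list alone: Bbc3, a death-promoting BCL2 family gene (34.5 ± 4.74 to 61.8 ± 6.80 CPM, SD, n = 3, log2 change 0.84, SE 0.16, adjusted p = 0.0144), and Plk2 (0.85, SE 0.20, adjusted p = 0.0361). The list was not called (camera adjusted p = 0.125). Among 7 proliferation genes (4 over the list alone), Mki67, a marker of dividing cells, rose from 0.315 ± 0.0319 to 1.43 ± 0.476 CPM (SD, n = 3, log2 change 2.17, SE 0.36, adjusted p = 0.00835), while Ccnd1 (cyclin D1), whose peak overlaps LTO1, was lower (-0.89, SE 0.23, adjusted p = 0.0477), and the list was not called (camera adjusted p = 0.345). Autophagy and mitophagy genes were called at 0 of 15 members by edgeR and 1 by DESeq2 (Tfeb, lower), with 4 at an unadjusted p below 0.05 and 0 over the list alone (camera adjusted p = 0.345). Bbc3 was not called without cadmium or control replicate 3 (adjusted p 0.0528 and 0.0579), Plk2 was called only without control replicate 2 (0.0644 to 0.118 in the others), and Ccnd1 was called in 0 of 6 leave-outs (0.0611 to 0.115).

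The peaks of a changed gene moved together. In 786 genes with a called peak and at least 1 other peak, 2743 of 2868 other peaks (95.6%) had the direction of the leading peak, against 49.9% for random peaks, and in 735 genes (93.5%) all peaks did. Across these peaks, which are not independent replicates, the log2 changes of other and leading peaks correlated at r = 0.909. In the within-gene test 13 of 29951 peaks departed from the other peaks of their gene, in 11 genes. In simulated counts the same test called 16 of 28891 peaks in genes with no departure. Those counts also held many planted 4-fold departures, so the 16 does not tell how many of the 13 are false. Single departing peaks stay uncertain. Chosen after the values were seen, 2 peaks of Per2 (chromosome 1, 91442958 to 91443063 and 91443953 to 91444080) had log2 changes of 0.18 and 0.34, each against a median of -2.07 at its other 9 peaks. Their level was low, 1.38 ± 0.250 and 1.28 ± 0.158 CPM in control samples (SD, n = 3). A peak of Cd163, a scavenger receptor gene of macrophages, had 0.27 against -3.43, and peaks of Rhobtb1 (1.46 against -0.95) and Acsm1 (-1.21 against 0.08) departed in either direction. The call of that Rhobtb1 peak was lost without cadmium replicate 1 or 3 or control replicate 1 or 3 (adjusted p 0.053 to 0.0632).

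Calls leaned to one direction on 6 chromosomes by Fisher's exact test, two-sided. Higher peaks made up 39.7% of calls on chromosome 5 (adjusted p = 2.29e-05), 44.4% on chromosome 4, 41.6% on chromosome 19 and 46.5% on chromosome 2, and 70.2% on chromosome 7 and 69.0% on chromosome 11. With 1 peak per gene, 0 chromosomes passed (0 also at an unadjusted p below 0.05) with the smallest adjusted p at 0.849.

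The authors' deposited table called 986 peaks higher and 587 lower. A p-value below 0.05 with at least a 2-fold change matched those calls in all 37118 rows, and the largest adjusted p among them was 0.232. Of the 1573 calls of the authors' deposited table, 1398 had an adjusted p below 0.05 in it, and so had 3683 peaks in all. Of the authors' calls 1160 were also called here, and 1151 of the 1161 peaks called here with at least a 2-fold change were among the authors' calls. DESeq2 run on the 6 count columns gave the fold changes of the authors' deposited table to within 1.2e-09 on the log2 scale.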

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

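The fit without TMM, that without the largest 2 peaks, 1 peak per gene for chromosomes, and the block and leave-outs for lists were chosen after seeing the data, as were all alternatives for direction except an adjusted p below 0.01, an unadjusted p below 0.05, the 2-fold change and the median level. The count of 2325 peaks was 3144 with the replicate block (2249 shared), 3683 with DESeq2 (2315 shared), 2290 without the filter, 2330 without the largest 2 peaks and 1624 without TMM. It ranged from 543 to 1976 when 1 sample was left out. It was 568 at an adjusted p below 0.01, 4050 below 0.10, 8086 and 3905 at an unadjusted p below 0.05 and 0.01, 1161 with at least a 2-fold change, 1244 at or above the median level and 1116 with 1 peak per gene. No called peak changed sign under the block, DESeq2, the filter, scaling or leave-out settings. The share of higher calls (56.6%) turned below an even split at an adjusted p below 0.01 (49.1%), at or above the median level (44.4%) and without control replicate 1 (49.3%), and ranged from 49.3% to 58.0% over the leave-outs. It was 66.3% without TMM, which moved the median log2 change from -0.003 to 0.036, and 63.4% over genes, both chosen after seeing the data. The cause was not tested. With an estimated correlation 0 lists passed in place of 10, and leave-outs gave 10 to 12. The block gave 11, adding metal handling. Chromosomes with a lean went from 6 to 0 with 1 peak per gene. Of 67 called peaks named by the rule set beforehand, 37 were called in all 6 leave-outs. The replicate block ended the call of Srebf1 among these 67 (adjusted p = 0.0577) and of no other. At this depth and spread the simulated test found 52% of 2-fold changes. It made 164 calls against 2325 here, so its cut-off was stricter and the share found here may be higher. A peak that was not called may still differ 2-fold. Tests of input RNA, the motif and transcript regions were not run, as no input counts or genome sequence were used.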

Other observations

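The tests of interferon genes, cell type markers, collagen genes, clock genes and sex-biased genes below were chosen after their values were seen. The glucocorticoid list was fixed before its members' values were looked at.

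Genes of interferon response and antigen presentation rose at 12 of 30 measured members of a list made after rises were seen, and 29 of 30 log2 changes were above 0. Cd74, the invariant chain of MHC class II (log2 change 1.73, SE 0.19, adjusted p = 0.0012), H2-Aa (1.58, SE 0.19, adjusted p = 0.00192), the class II activator Ciita (1.09, SE 0.24, adjusted p = 0.0247) and the interferon-induced genes Gbp10 (1.86, SE 0.16, adjusted p = 0.000883) and Oasl2 (1.59, SE 0.19, adjusted p = 0.00163) were higher. The class I genes H2-K1 (0.25), H2-D1 (0.34) and B2m (-0.09) were not called. The list is not independent evidence, since rises led to it. Its camera p was 9.13e-14, and p = 0.076 with an estimated correlation. Of 6 markers of Kupffer cells and macrophages, 3 were called higher in the same samples and 2 had changes below 0. Ciita was not called without cadmium replicate 2 or 3 or control replicate 1 or 3 (adjusted p 0.058 to 0.126). Among other called members, Irf1 was called in 1 of 6 leave-outs, Oas1a and Isg15 in 2, Tap1 in 3 and Ifit3 in 4. Cd74, H2-Aa, Gbp10 and Oasl2 were called in all 6.

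Cd163, a macrophage gene, fell. Its leading peak (chromosome 6, 124312411 to 124312575) had a log2 change of -4.05 (SE 0.32, adjusted p = 0.000832), from 3.29 to 0.20 CPM, and 5 of its other 6 peaks were also lower, while the macrophage markers Lyz2, Cd5l and Csf1r rose and Vsig4 (-0.81) and Marco (-0.35) were not called. The sulfotransferase gene Sult3a2 (4.01, SE 0.36, adjusted p = 0.000883) and its neighbour Sult3a1 (1.87, SE 0.18, adjusted p = 0.000957) rose together with A1bg.

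The first pattern weighed is the set of called peaks. Of the 10 splits of the 6 samples into 3 and 3, the real one called 2325 peaks and the highest other called 0, though the others had 217 to 2213 peaks at an unadjusted p below 0.05. The 1 real split was the only one as large, and 10 splits are too few for a share under 0.05. The same holds for 13 departing peaks (highest other 0) and 10 called lists (highest other 9). The 3 other splits that part every batch, as the real one does, called 0 peaks and 4 to 9 lists. The other 9 splits each called 1 to 9 lists, and each joins 2 samples of one treatment with 1 of the other. Of the leading called peaks 0.891% departed from the other peaks of their gene, below the 10% set beforehand as the bound. Recovery by that test was simulated only for 4-fold departures (87.5%), so smaller ones could be missed. The simulated counts held many planted departures, so the cut-off there was looser than here, where 13 peaks departed. Recovery of 4-fold departures at the cut-off used here may be lower and was not measured. Of the 2325 called peaks, 1161 changed at least 2-fold. The low share therefore argues only against large changes at single peaks as the main account, in genes with several single-symbol peaks. A change in the RNA level of whole genes may account for most calls, since 95.6% of the other peaks moved the same way, though a shift in the methylated share of a whole transcript would look alike without input counts.

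The second pattern is the clock. The median absolute log2 change of the 13 members was 5.02 times their median spread within groups, with Per2, Per3, Ciart and Hlf lower and Nr1d1 higher. This used the peak with the smallest p of each gene, a choice that favours a large ratio. Livers of the 2 groups collected at different hours could give this, and so could a shift of the clock or of feeding times under cadmium. The labels give no hour of collection, so these cannot be told apart. The 13 rhythmic genes of another list, Noct, Wee1 and Tsku among them, all fell, but they were chosen because they fell and test nothing. That list also holds Alas1, Cyp7a1 and Por, described above for their metabolic roles, so an unequal hour of collection stays open for their falls too. It stays open likewise for every other change reported here, in any list, at a gene whose RNA varies over the day or with feeding. Which of the other genes do so was not examined.

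The third pattern is the rise of markers of other cell types with collagen genes. A lower share of hepatocytes would raise markers of every other type alike. With the peak of highest level per gene, mean log2 changes were 1.02 for cholangiocyte, 0.44 for macrophage, 0.35 for endothelial and 0.45 for stellate markers, and a permutation test over genes did not separate them (p = 0.198), so for these markers the hepatocyte share stays open. The 4 collagen genes of the fibrosis list, all its collagen members, rose by 1.69 on average against 0.45 for 8 stellate markers (exact two-sided permutation p = 0.00202 over genes). The smallest of their changes (1.14) was above the largest of the stellate markers (0.77). These 4 were singled out after their rise was seen, so this test cannot decide whether a lower hepatocyte share was the whole cause for them. In a test added later, all 15 collagen genes with a peak, some with changes below 0, had a mean of 0.78 (SD 0.85) and were not separated from the stellate markers (exact two-sided permutation p = 0.305), so for collagen genes in general the hepatocyte share stays open. Higher collagen expression per stellate cell also stays open and was not tested.

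As a hypothesis, lower glucocorticoid signalling may link the falls of Tat, Pck1, Igfbp1, Per1 and Cd163, which glucocorticoids can induce. In a list of other glucocorticoid-induced genes, 5 of 17 fell and 1 rose, with a median log2 change of -0.67. Fkbp5 (-0.99, SE 0.22, adjusted p = 0.0247), Zbtb16 (-1.13, SE 0.25, adjusted p = 0.0257) and Cebpb (-1.09, SE 0.21, adjusted p = 0.0161) were lower, each not called without cadmium replicate 3 among others (adjusted p up to 0.125), and Rgs2 was higher (1.37, SE 0.23, and adjusted p = 0.0605 without cadmium replicate 3). The list test gave p = 0.00151 with the preset correlation, which met the prediction as set beforehand, and p = 0.0712 with an estimated correlation. Glucocorticoids vary over the day, so an unequal hour of collection could act here too and stays open.

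A shift from the male to the female liver pattern was considered for the rise of A1bg and Sult3a1, which are higher in female mouse liver. Of 12 other female-biased genes 2 were higher, Sult3a2 and Cyp2c69 (0.83, not called with the replicate block, adjusted p = 0.0553, and called in 1 of 6 leave-outs, adjusted p up to 0.134 in the others), and 2 lower, Acot3 (-1.43, SE 0.18) among them, with a median log2 change of -0.35, a mean of 0.13 and camera adjusted p = 0.191. Of 12 male-biased genes 1 was higher, Selenbp2 (0.88, called in 3 of 6 leave-outs), and 2 lower, Susd4 (-1.66, adjusted p = 0.0553 without cadmium replicate 3) and Gstp1 (-0.68, adjusted p up to 0.0892 without cadmium replicate 2 or 3 or control replicate 3), with a median of -0.30 (camera adjusted p = 0.191). Genes of both lists moved both ways, so a shift of part of the pattern stays open.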
